A study of Glycine max with 8 samples.

How the data were processed

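ChIP-seq peak lists of a soybean WOX9-like protein were compared between whole seeds with globular embryos and whole seeds with heart-stage embryos. Of the 8 libraries, the 4 ChIP libraries (2 per stage) have a peak list each, called per library and not on pooled replicates. The 4 input libraries have no list of their own and were not analysed here as samples. Per the labels' protocols, chromatin was cross-linked with formaldehyde, sheared by sonication and precipitated with a polyclonal peptide antibody, and libraries were amplified by PCR.

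Per the submitters' processing notes, Bowtie 0.12.7, SAMtools 0.1.18 and MACS2 were used, with no roles or settings. The genome build, the control of each ChIP library, the treatment of duplicate reads and the calling threshold are not given in the sources used here. The deposited files are in the narrowPeak layout. Their fold column is a ratio, the fold enrichment at the summit over the local background, and the deposited p and q columns are −log10 p and −log10 q at the summit. The deposited score is the whole part of 10 times −log10 q, in 100% of the rows. The lowest −log10 q was 2.00 to 2.04 in the 4 lists. The run name inside the peak names of globular replicate 2 differs in form from the other 3 and holds the words BR1 and Input. No label explains it, so whether it refers to the control or to the replicate is not known, which bears on each comparison between the globular replicates. The title of the globular replicate 2 input lacks the words WOX9 study, which the titles of the other 3 inputs hold.

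Positions are those of the files, counted from 1. Their build is not named. The files write chromosomes as Chr01 and so on, and the reference gene table at hand belongs to the assembly Glycine_max_v4.0. The coordinates could not be shown to match that assembly. On 5 of 20 chromosomes peaks lay beyond its last protein-coding gene. Of the summits, 9.31% to 9.39% lay within 300 bp of a gene end, against 9.57% to 9.71% after moving the summits by 7000 bp. These values do not settle whether the builds differ, since chromosome lengths and sequence were not compared. Peaks were therefore not assigned to genes. The planned comparisons of genomic features, bound genes, gene lists and sequence motifs need an annotation or sequence of the build of the files and were not run. The gene lists fixed for them have no result.

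Depth is not given in the files. The recovery described next was added after the data had been seen. Under the formulas of MACS2 (fold as pileup plus 1 over background plus 1, p from the Poisson distribution), the fold and p of a peak fix the pileup and background behind them. In both globular libraries 100% of the peaks gave a whole-number pileup, within 0.002 in −log10 p, with a median of 35 reads in replicate 1 and 67 in replicate 2. In the heart libraries 0.053% and 0.0555% did, and the pileups there moved in steps of 0.70 in replicate 1 and 0.82 in replicate 2. The floor of the background, its 0.5 percentile over 8000 peaks drawn at random from each list, divided by that step (1 in the globular libraries), was used as the depth index. It assumes that these formulas were used as published. A single flat background explained, within 0.01 in −log10 p, 91.4% and 91.7% of the peaks of heart replicates 1 and 2, and 11.1% and 15.1% of those of globular replicates 1 and 2. Folds of the stages therefore rest on differently built backgrounds and are used only within a list. Peaks with −log10 p of 250 or more were left out of this recovery.

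Peaks of different libraries were counted as shared when they overlapped by at least 50% of the shorter peak, and connected peaks formed a region. A region held 2 or more peaks of one library in 5.51% of cases. A region was stage-only when both libraries of one stage and neither of the other had a peak in it. The same count for the 2 partings that mix the stages was set beside it. Expected overlaps came from 100 seeded shifts. The planned circular shifts along whole chromosomes gave 3.27% for globular replicate 1 and 4.06% for heart replicate 1, and shifts of 20000 to 100000 bp, added after the data had been seen, keep the regional density. The difference between within-stage and across-stage Jaccard indices was tested exactly over the 3 partings. Positions along a chromosome are relative to the last base with a peak, and classes were compared by permuting the signs of the differences over 20 chromosomes. That comparison, the distances to neighbouring regions and the shifts in rank were added after the data had been seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used. On 118000 simulated peaks with summits scattered by 40 bp (SD), 100% of 20000 regions of 4 libraries, 2999 of 3000 globular-only and 7998 of 8000 heart-only regions were recovered, with 0 in the mixed partings. The simulated sites were kept apart and called in every library of their class, so close neighbours and missed calls were not tried. The count of 0 follows from that setting.

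The rule for named regions was fixed before the data were examined, as were the gene lists, the tests and the alternatives except those named as added. In the absence of an annotation it takes 10 regions from each of 3 classes (all 4 libraries, globular only, heart only) by their worst rank percentile of fold over the libraries that called them. Alternatives were an overlap of 1 bp, summits within 100 bp, peaks with −log10 q of at least 5, the same number of peaks from each library, the top 10000 peaks, the omission of each replicate and a comparison of stages within replicate numbers. The 2 libraries of a stage had 1 or 2 peaks with identical start and end, so the lists are not copies of each other.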

Results

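Chromatin bound by a WOX9-like protein was profiled in whole seeds of soybean (Glycine max, cultivar Williams 82) at 2 stages of early embryo development. WOX9-like belongs to the WUSCHEL-related homeobox family, plant homeodomain transcription factors known for their part in embryo patterning and meristem growth. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with a rabbit antibody against a peptide of the protein. Seeds of 1.0 to 1.5 mm held globular embryos, and seeds of 1.7 to 2.1 mm held heart-stage embryos, in which the cotyledons have begun to form. Each stage had 2 ChIP libraries and 2 input libraries, and the comparisons rest on the peak lists of the 4 ChIP libraries. The labels call the libraries of a stage replicates without saying whether they came from separate plants, so the spread between them may be technical. Whole seeds contain seed coat and endosperm beside the embryo, and the peaks cannot be assigned to one of these tissues.

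The WOX9-like antibody gave enriched sites on all 20 chromosomes in every library. Globular replicate 1 had 46027 peaks and globular replicate 2 had 44581. Heart replicate 1 had 60537 peaks and heart replicate 2 had 50579. The sites were short: the median peak width was 433 bp and 468 bp in the globular libraries and 476 bp and 451 bp in the heart libraries. Peaks covered 22.5 Mb and 25.3 Mb at the globular stage and 35.8 Mb and 27.8 Mb at the heart stage. The median fold enrichment at the summit, as given by the authors' peak caller, was 5.61 and 3.63 in globular replicates 1 and 2, and 4.99 and 4.98 in heart replicates 1 and 2. Between 0.558% and 0.579% of the peaks of a library lay on unplaced scaffolds. The files give no read totals. A depth index was taken from the floor of the background that the fold and p of the peaks imply under the caller's formulas. This floor was divided by the step of the pileups, which was 1 in the globular libraries. The index was 4.34 for globular replicate 1, 15.2 for globular replicate 2, 9.09 for heart replicate 1 and 9.05 for heart replicate 2. The globular libraries differed more in this index than the heart libraries.

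The first question was how well the sites of one stage were found again in its second library. At the heart stage, 75.9% of the peaks of replicate 1 were shared with replicate 2 and 94.1% of the peaks of replicate 2 were shared with replicate 1. At the globular stage the values were 76.4% and 75.9%. Peaks moved together by a random distance of 20000 to 100000 bp along their chromosomes were shared far less often, 7.50% for heart replicate 1 and 6.20% for globular replicate 1 (means of 100 shifts, with maxima of 7.72% and 6.48%). The heart libraries also ranked their sites alike, with a Spearman correlation of fold enrichment of 0.92 over 43368 shared peaks. The correlation was 0.43 over the 32188 peaks shared by the globular libraries. These correlations run across peaks, which are not independent replicates, and no p is given for them.

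Strong globular sites were mostly called in both globular libraries, and globular replicate 1 differed from the other libraries in how many of its strong sites were called at the heart stage. Of the top 10% of peaks in globular replicate 1, 97.2% were called in globular replicate 2, and of those in globular replicate 2, 100% were called in replicate 1. In the weakest 10% these shares were 63.7% and 43.7%. Of the top 10% of peaks in globular replicate 2, 99.8% were also called in both heart libraries, and the top 10% of the heart libraries were called in both globular libraries in 99.6% (replicate 1) and 99.9% (replicate 2) of cases. Of the top 10% in globular replicate 1, 62.2% were called in both heart libraries and 20.5% in neither. In globular replicate 2 and both heart libraries, the share of peaks called at the other stage fell with each step down the list, to 56.7% in the weakest 10% of globular replicate 2, 13.5% in that of heart replicate 1 and 22.7% in that of heart replicate 2. In globular replicate 1 the share was 68.3% in the weakest 10%, above that of its strongest peaks, and between 20.5% and 29.1% of the peaks in each of the 10 parts of the list were called in neither heart library.

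**Figure D1:**
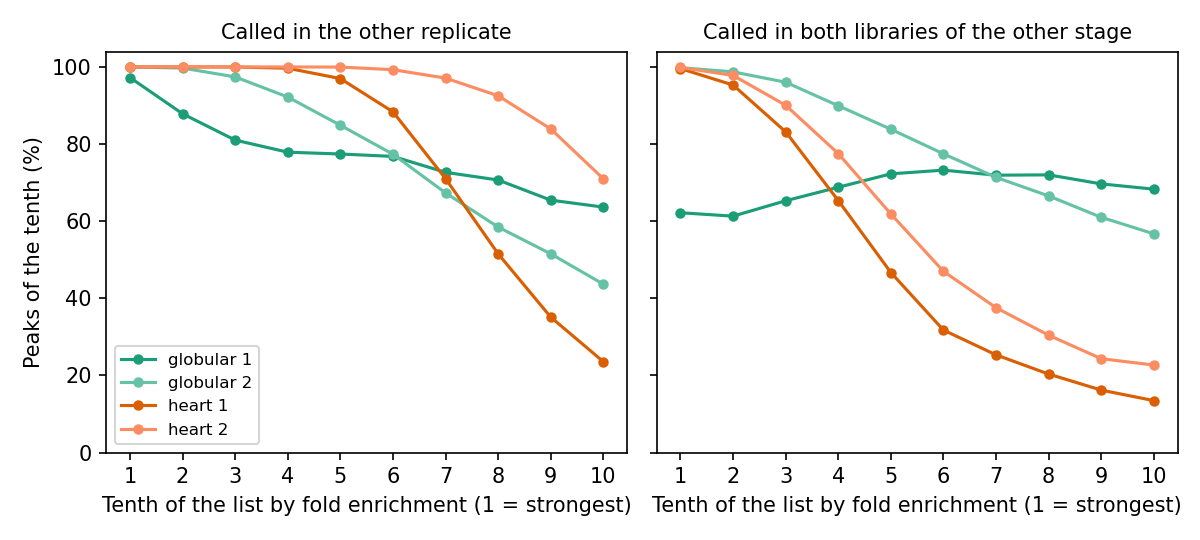
Each list was ranked by fold enrichment and divided into 10 parts (x axis, 1 is the strongest). Points give the percentage of peaks in a part that were called in the other replicate of the stage (left) or in both libraries of the other stage (right); only globular replicate 1 starts low on the right, at 62.2%.

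The central comparison asked which WOX9-like sites were called at both stages and which at 1 stage only. A missing call does not show that a site was unoccupied. Joined across the 4 libraries, the peaks made 75046 regions, of which 27270 (36.3%) were called in all 4 libraries. Both globular libraries called 32967 regions, and 82.7% of these were called in both heart libraries and 89.5% in at least 1 of them. Both heart libraries called 45216 regions, of which 60.3% were called in both globular libraries and 79.5% in at least 1. In regions with a single peak from each library (23640 regions), the summits lay a median of 27 bp apart between the heart libraries, 37 bp between the globular libraries and 32 to 39 bp across the stages. Summits of a shared site were thus about as far apart across stages as between the globular replicates.

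On average, libraries of the same stage shared more sites than libraries of different stages. The Jaccard index (shared regions over all regions of a pair) was 0.61 within the globular stage and 0.72 within the heart stage. Across stages it was 0.45 and 0.47 for globular replicate 1 with heart replicates 1 and 2, and 0.57 and 0.61 for globular replicate 2. The mean within stages exceeded the mean across stages by 0.14. Of the 3 ways to part the 4 libraries into pairs, the parting by stage gave the largest difference, and the other partings gave -0.07 and -0.08. The exact permutation test (one-sided) gave p = 0.333, the smallest value that 4 libraries allow, so the design cannot reach 0.05. Globular replicate 2 shared about as many sites with heart replicate 2 (0.61) as with its own replicate (0.61). Among the top 10000 peaks of each library, the index was 0.323 for the globular libraries, against 0.651 and 0.645 for globular replicate 2 with heart replicates 1 and 2. The mean difference over all peaks was 0.07 without heart replicate 1 and 0.27 without globular replicate 2.

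Among regions called in all 4 libraries or in both libraries of a single stage, those in the top 10% of every list that held them were mostly common to both stages: 1626 were called in all 4 libraries, 1 in the globular libraries only and 5 in the heart libraries only. The globular-only count is limited by globular replicate 2, where 5 peaks of the top 10% were called in neither heart library. In globular replicate 1 there were 943 such peaks, so the count does not show that its strong sites were common to both stages. By the worst of its 4 rank percentiles, the first region of all 4 libraries was on chromosome 18 from 57421110 to 57425436, with a fold enrichment of 53.0 and 29.5 in globular replicates 1 and 2 and of 44.4 and 43.2 in heart replicates 1 and 2. In heart replicate 1 it ranked behind the next region named. A second region of chromosome 18, from 57415626 to 57416657, was the third by the same rule, with a fold of 41.6 and 22.0001 in globular replicates 1 and 2 and of 44.7 and 41.9 in heart replicates 1 and 2, its place being set by its percentile of 0.0292 in globular replicate 2. Chromosome 13 held the second region (14062569 to 14063860, fold 40.2, 29.4, 40.3 and 37.9 in the same order of libraries) and the fourth (23039803 to 23041436). The others among the first 10 were on chromosome 1 (52469357 to 52471662), chromosome 4 (20432930 to 20433736), chromosome 15 (1008056 to 1009882), chromosome 5 (38886679 to 38887343), chromosome 8 (47619764 to 47625169) and chromosome 11 (3951253 to 3952527). The folds are the authors' values for each library and rank sites within a list. All 10 regions were within the top 0.126% of every list, and the summits of a region differed by at most 47 bp between libraries. The regions could not be assigned to genes, because no annotation of the genome build of the files was used here.

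At the globular stage, 3469 regions were called in both libraries and in neither heart library. They were strong in globular replicate 1, with a median rank percentile of 20.3 (0 is the strongest), and weak in globular replicate 2, with a median of 70.8. Regions called in all 4 libraries had medians of 47.4 in globular replicate 1 and 32.4 in globular replicate 2. The globular-only regions thus ranked above them in replicate 1 and below them in replicate 2. The highest-ranked was on chromosome 17 from 40701588 to 40703120, with a fold of 15.8 in replicate 1 and 13.5 in replicate 2. It was followed by regions on chromosome 2 (14878039 to 14878950, fold 13.6 and 7.74), chromosome 11 (15569011 to 15569559, fold 20.02 and 7.49), chromosome 7 (16671965 to 16672972, fold 11.2 and 7.86) and chromosome 16 (32485014 to 32485936, fold 25.7 and 6.96). The remaining 5 of the first 10 lay on chromosome 20 (34191461 to 34192017), chromosome 6 (9967506 to 9968104), chromosome 10 (31005932 to 31006508), chromosome 9 (43649526 to 43650157) and chromosome 7 (42423702 to 42424230). The chromosome 2 region overlapped a peak of heart replicate 1 by less than 50% of the shorter peak, with summits at least 419 bp apart, and was the only one of these 10 with any heart peak over it. The number of globular-only regions depended on the libraries required. It was 11077 without globular replicate 2 and 5363 without heart replicate 1, where fewer libraries set the class. Such a count can only rise when a library is left out, so it does not test the 3469 regions.

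At the heart stage, 9254 regions were called in both libraries and in neither globular library, 2.67 times the globular number. They were among the weaker heart sites, with a median rank percentile of 64.1 in replicate 1 and 75.2 in replicate 2, against 23.8 and 29.0 for regions called in all 4 libraries. The highest-ranked was on chromosome 15 from 1600077 to 1600630, with a fold of 18.9 in replicate 1 and 13.5 in replicate 2. Next were regions on chromosome 1 (51260935 to 51261482, fold 13.6 and 12.5), chromosome 2 (43431127 to 43431708, fold 15.0 and 12.5), chromosome 4 (6701981 to 6702502, fold 15.8 and 12.5) and chromosome 18 (3092415 to 3093474, fold 17.6 and 11.8). The other 5 lay on chromosome 20 (3200337 to 3200921), chromosome 13 (32765463 to 32766554), chromosome 2 (5116251 to 5116753), chromosome 5 (32171477 to 32172032) and chromosome 8 (45190324 to 45190781). With an equal number of peaks taken from each library (the best 44581 by p), the heart number was 5631 and the globular number 5159, a ratio of 1.09. The cut also removes weaker heart peaks, so regions with such a peak can enter the globular number, which was 3469 with all peaks. The ratio therefore does not isolate the effect of list length. The heart-only number was 16190 without globular replicate 2 and 19338 without heart replicate 2, where fewer libraries set the class.

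With all peaks, pairs that mixed the stages had fewer regions of their own than the same-stage pairs. Globular 1 and heart 1 alone shared 1025 regions, globular 2 and heart 2 alone 229, globular 1 and heart 2 alone 151, and globular 2 and heart 1 alone 1309. The 2 mixed partings of the libraries thus gave 1254 and 1460 regions in all, against 12723 for the parting by stage. With summits within 100 bp the mixed partings gave 2064 and 2302, against 4498 globular-only and 9596 heart-only regions. Among the top 10000 peaks they gave 307 and 351, each a total over 2 pairs. The globular pair alone gave 390 and the heart pair alone 1437. Absence there means absence from the top 10000 of the other lists, so such regions can have a weaker peak at the other stage. A mixed parting places the closely matched heart libraries on opposite sides, which by itself keeps its count low.

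**Figure D2:**
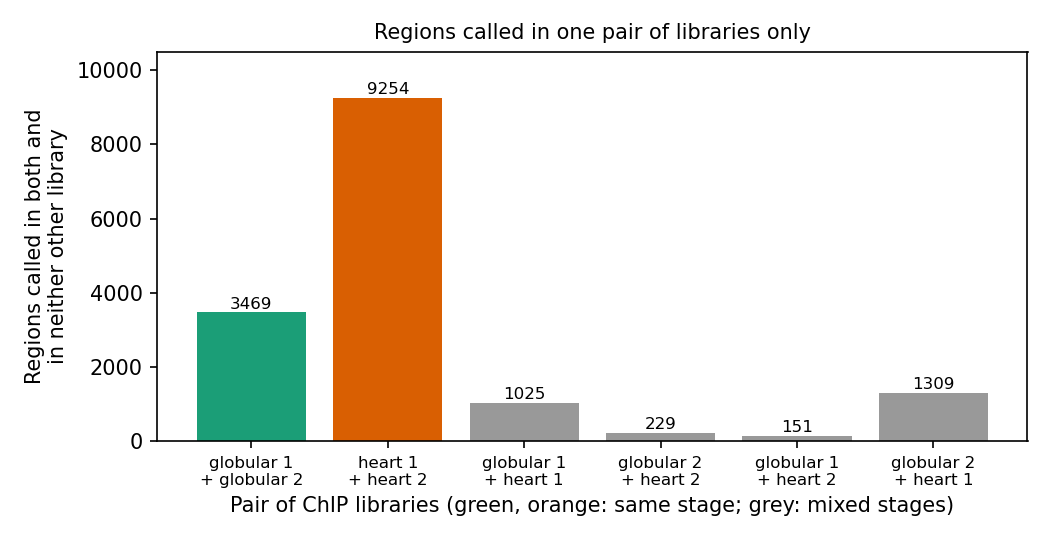
Bars give the number of regions called in both libraries of a pair and in neither of the other libraries (y axis), for each of the 6 pairs (x axis). The same-stage pairs had 3469 and 9254 regions, and the mixed pairs between 151 and 1309.

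WOX9-like sites were concentrated toward the chromosome ends. They were not compared with gene density or input reads, so the concentration is not shown to be particular to this protein. Of the regions called in all 4 libraries, 69.9% lay in the outer 20% at either end of a chromosome, which together make up 40% of its extent, and 2.28% lay in the sixth of 10 equal parts. Density ranged from 21.7 regions per Mb on chromosome 18 to 43.7 on chromosome 13, where only 36.6% of the regions were in the outer part. Heart-only regions showed no detectable difference from these: their mean share in the outer part was 71.6% ± 10.4 (SD, n = 20 chromosomes), against 71.3% ± 10.9 for regions of all 4 libraries, a difference of 0.304 points (p = 0.633, adjusted 0.633, higher on 11 of 20 chromosomes; two-sided permutation test over chromosomes). Globular-only regions were in the outer part slightly more often, 73.9% ± 12.2, which was 2.65 points above regions of all 4 libraries (p = 0.00162, adjusted over 3 comparisons 0.00486, higher on 16 of 20 chromosomes) and 2.35 points above heart-only regions (p = 0.0236, adjusted 0.0354, higher on 14 of 20; permutation tests as before). Neither globular difference kept its size when a globular library was left out. Such an omission also changes the classes: globular-only then meant 5055 regions without globular replicate 1 and 11077 without globular replicate 2. The values without a library therefore do not test the 3469 regions, and the differences are not shown to be stable. In the same permutation test, the difference from regions of all 4 libraries was 0.50 points without globular replicate 1 (p = 0.468) and -0.297 points without globular replicate 2 (p = 0.572), and the difference from heart-only regions was 0.707 points (p = 0.347) and -1.16 points (p = 0.112). These comparisons of position were chosen after the data had been seen. Their p-values measure the spread between chromosomes of the same 4 libraries, not between seed samples.

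**Figure D3:**
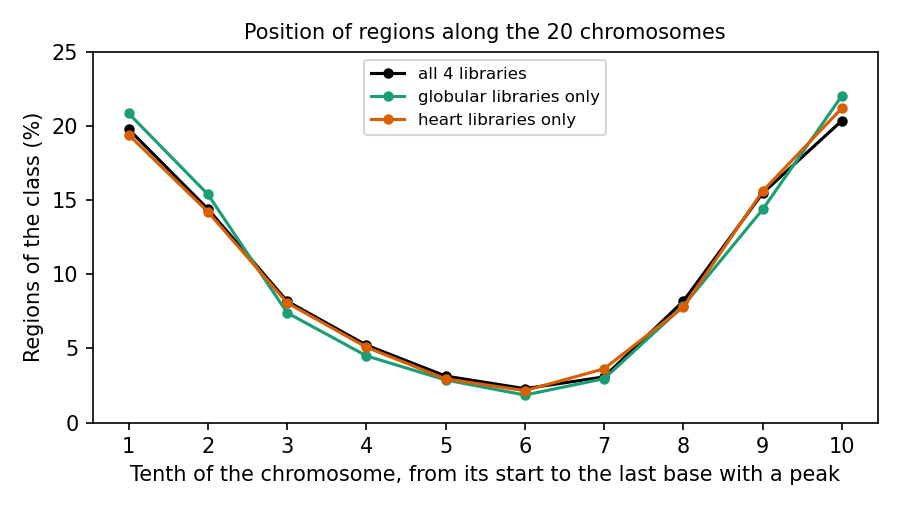
The x axis divides each of the 20 chromosomes into 10 equal parts, and the y axis gives the percentage of a class of regions in each part. All 3 classes are lowest in the sixth part, with 2.28% of the regions of all 4 libraries.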

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

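The comparison of positions, its alternatives, the Jaccard values without single libraries and the filter on rank percentile were chosen after the data had been seen, and the other alternatives before. The stage difference in Jaccard index stayed above 0 under all 5 other settings of overlap and threshold (0.10 to 0.16) and without each library (0.07 without heart replicate 1 to 0.27 without globular replicate 2). With a replicate block, which compares stages only within a replicate number, it was 0.14. The labels tie no replicate number across stages, and the differences in log2 fold between replicates 1 and 2 had a correlation of -0.04 between stages (Pearson, across 23640 regions, which are not independent). The mean share of peaks found in both globular libraries fell from 76.1% to 64.9% with summits within 100 bp and to 49.1% among the top 10000 peaks. The heart share, 85.0% with all peaks, was 74.4% with summits within 100 bp and 90.1% among the top 10000 peaks. Heart-only regions numbered 5631 and globular-only regions 5159 with equal list lengths, where absence was judged in the shortened lists. Among the top 10000 peaks there were 4307 regions of all 4 libraries, 390 globular-only and 1437 heart-only regions, fewer by construction. Absence was judged there within the top 10000 only, so these stage-only regions can have a weaker peak at the other stage. With presence at −log10 q of at least 5 and absence at any level, there were 3191 globular-only and 7532 heart-only regions. Within the stronger 50% of both lists of a stage, with no peak at any level at the other stage, 530 globular-only and 845 heart-only regions were left. Leaving out 1 library gave 3803 to 11077 globular-only regions, with 11077 without globular replicate 2 and 5363 without heart replicate 1, and 11010 to 19338 heart-only regions, with 16190 without globular replicate 2 and 19338 without heart replicate 2; a region then needs fewer libraries. The larger share of globular-only than of all-library regions in the outer chromosome parts ranged from -0.297 to 2.72 points with 1 library left out, and was 0.50 points without globular replicate 1 and negative without globular replicate 2. The difference between globular-only and heart-only regions ranged from -1.16 to 3.05 points with 1 library left out. It was smaller without globular replicate 1 and negative without globular replicate 2, where fewer libraries set the classes. With the outer 10% at each end it was 2.19 points (permutation p = 0.125). The cause was not tested. Of the 30 named regions, 29 kept the same set of libraries with a peak over them when 1 bp of overlap counted, and all 30 did so with summits within 100 bp; the settings that only remove weaker peaks do not test these regions, which were chosen by rank. What depth limits could not be measured without read totals; the depth index was 4.34 and 15.2 in the globular libraries and 9.09 and 9.05 in the heart libraries. Comparisons of genomic features, bound genes, gene lists and motifs were not run.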

Other observations

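The comparisons of widths, neighbouring regions and ranks, and the tests of ChIP depth, the calling threshold, false calls and equal strength, were chosen after the results they bear on had been seen. The bounds for the raised heart background and for the ranking of globular replicate 1 by pileup were written before.

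Among regions called in all 4 libraries, the widest covered 10792 bp of chromosome 14 (6622097 to 6632888) and held 5 peaks in globular replicate 1, 1 in globular replicate 2, 1 in heart replicate 1 and 2 in heart replicate 2. The next covered 10070 bp of chromosome 2 (1898099 to 1908168) and held 8 peaks in globular replicate 1, 5 in globular replicate 2, 2 in heart replicate 1 and 1 in heart replicate 2. Peaks of 3000 bp or more numbered 8 and 40 in globular replicates 1 and 2, and 173 and 92 in heart replicates 1 and 2. These regions were singled out after their values were seen.

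Heart-only regions lay within 2000 bp of sites called in all 4 libraries more often than redrawn positions did. Of the 9254 heart-only regions, 24.99% had a region of all 4 libraries within 2000 bp, against 14.8% for positions redrawn within a window of 100000 bp, at least 500 bp from such a region (highest of 100 draws, 15.9%). For the 3469 globular-only regions the value was 18.2%, against 16.4% redrawn (highest 17.7%). Regions of the mixed pairs also exceeded their redrawn positions. The share was 31.0% for globular 2 and heart 1 (redrawn 16.0%, highest 17.9%) and 20.7% for globular 1 and heart 1 (15.7%, highest 19.2%). It was 30.1% for globular 2 and heart 2 (16.1%, highest 22.3%) and 27.8% for globular 1 and heart 2 (16.3%, highest 22.5%). The excess was thus not particular to heart-only regions. The difference between the classes was not tested.

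The ranks of shared sites were compared as well. In the 23640 regions with 1 peak per library, ranked within that set, 1365 were at least 20 percentile points stronger in both globular than in both heart libraries, and 1202 were so in the heart libraries. The partings that mix the stages gave 93 and 102 in all, a count kept low by the close match of the heart libraries (Spearman 0.95 over these regions). The ranks rest on folds, and a flat background explained 91.4% and 91.7% of the heart peaks against 11.1% and 15.1% of the globular peaks, so these shifts in rank are not read as stage differences. The correlation between the globular libraries was 0.65, below the 0.75 of globular replicate 2 with either heart library. By this measure globular replicate 1 was the least like the other 3. It also had the lowest depth index, 4.34 against 15.2 in globular replicate 2 and 9.09 and 9.05 in heart replicates 1 and 2. These correlations rest on the same folds, and the part of depth or background in them was not tested.

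The first pattern weighed is the set of 9254 regions called in both heart libraries and in neither globular library. Greater ChIP depth of the heart libraries is argued against as the whole cause, because the depth index of globular replicate 2 was 1.67 times their mean and 11010 regions of both heart libraries were still not called there. Weak sites near the calling threshold stay open. Of the heart-only regions, 90.9% were in the weaker 50% of at least one heart list, against 24.9% of the regions of all 4 libraries. The lower of their −log10 q values in the heart lists had a median of 7.02, against 28.8 for regions of all 4 libraries. But 81.4% of the heart-only regions reached −log10 q of 5 in both heart lists, against 97.9% of the regions of all 4 libraries. The lowest values of the heart lists were near 2, and a heart q sets no level in a globular list. The flat heart background was then raised to the 95th percentile of what the globular peaks had, 1.71 times their floor. That would cost 28.5% of the heart-only regions and 3.75% of the regions of all 4 libraries. Raising it to their median, 1.16 times the floor, would cost 0.551% and 0.158%. The value of 28.5% is below the bound of 50% set beforehand for the background to be the cause. That bound is not read as excluding it, a choice made after the value was seen, because the uniform rise is an assumed profile taken from called peaks only; so the background, a lower yield of the globular immunoprecipitations and a gain of weak sites at the heart stage all remain open, and the yield and the gain were not tested.

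The second pattern is the strong peaks of globular replicate 1 that neither heart library called, 943 of the 4602 in its top 10%; the share, 20.5%, was no higher than in the other parts of its list, but was 0.112% in the top 10% of globular replicate 2. Random false calls in a shallow library are argued against, since 89.5% of these peaks were also called in globular replicate 2. Of all globular replicate 1 peaks, 6.20% were shared after shifting. False calls common to both globular libraries would recur too, so they are not addressed by this. A low local background that raises the fold is argued against as well, since 20.3% of its top 10% by recovered pileup were called in neither heart library. A stage difference of equal strength in both globular libraries is not what the ranks show: the median rank percentile of these peaks in globular replicate 2 was 56.0, against 5.52 for the peaks of the same top 10% that both heart libraries called. A set of sites that is strong in globular replicate 1, weak in globular replicate 2 and mostly not called at the heart stage may reflect a difference between the globular seed samples, a second protein seen by the antibody or a stage difference of unequal strength, and none of these was tested. The control of each globular library is not known, and its part in this pattern was not tested either.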
